A study of Danio rerio with 3 samples.

How the data were processed

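Single-nucleus RNA profiles of regenerating adult caudal fins of zebrafish (strain AB) were available for 3 libraries, a pilot from 25 fins and a main library from 100 fins at 3 days post amputation (dpa) and a library from 100 fins at 5 dpa. Per the labels' protocols, tissue was frozen, and nuclei were isolated, fixed with paraformaldehyde and taken through sci-RNA-seq3, in which oligo-dT primers start the reverse transcription of nuclear RNA. Per the submitters' processing notes, reads were handled with bcl2fastq 2.20, cutadapt 1.18, Trim Galore 0.6.5, STAR 2.5.2b and SAMtools 1.9 on genome build GRCz11. The deposited files hold raw UMI counts per gene and barcode, without normalization, for 25432 genes with Ensembl identifiers and symbols. The labels name neither the counting program nor the annotation release nor the filter on barcodes. Gene positions are not in the files and were not needed.

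The deposited files listed 8973 barcodes in the pilot, 340644 in the main 3 dpa and 573109 in the 5 dpa library, with at least 26 UMIs per barcode in the pilot and at least 1 in the others. Barcodes of at least 200 UMIs numbered 4097, 6500 and 12073 and held 92.3%, 83.4% and 85.1% of the UMIs. They had median depths of 521, 432.5 and 469 UMIs and of 405, 342 and 375 genes. Nuclei of over 5000 UMIs numbered 152, 282 and 389 and held 36.1%, 48.8% and 38.1% of the UMIs of those barcodes. Doublet scores were computed per library with Scrublet in scanpy. Its automatic threshold marked 0 nuclei, so nuclei with a score above the limit of the highest 5% were removed, 132, 304 and 559 nuclei, a choice made after the data were seen. This left 3965, 6196 and 11514 nuclei with 4703090, 8180520 and 13096400 UMIs.

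Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 was used for clustering and plots. UMIs were scaled to 1000 per nucleus, log-transformed, standardized within each library and clipped at 10. The 2000 most variable genes detected in at least 0.2% of nuclei gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 with seed 7. Genes with symbols starting with rpl, rps or mt- and the genes of the EMT and epithelial lists were left out of clustering, so that these lists did not define the classes. A cluster was named after 1 of 17 marker lists when at least 3 of its markers were at least 2-fold above the other nuclei and detected in at least 2% of the cluster's nuclei. These cutoffs for naming were set after the data were seen. The 8 named classes were osteoblast, fibroblast, basal epidermis, superficial epidermis, endothelial, macrophage, mucous and pigment, each followed by -like in the text, and 8 clusters stayed unnamed. Shares of nuclei have exact Clopper-Pearson 95% intervals, and levels in one library exact Poisson 95% intervals, both of counting error only. A count of 0 was read as an upper limit from the Poisson interval.

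For each comparison, UMIs were summed per library and class, with at least 30 nuclei in every library. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The test throughout was edgeR's quasi-likelihood test with TMM scaling, its filter on low counts and robust dispersions, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The time comparison set 1 library at 5 dpa against 2 at 3 dpa, which leaves 1 residual degree of freedom. The lone 5 dpa library is assumed to vary like the 3 dpa libraries, so folds against each 3 dpa library are given beside the fitted ones, with 0.5 added to each count. Comparisons of classes used the library as a block. The 14 program lists were tested by camera of limma with a correlation preset at 0.01 and again with an estimated correlation, adjusted over the lists of a class, and in comparisons of classes by fry of limma, adjusted over the 8 tests of list and comparison. Over time, with 1 residual degree of freedom, camera with an estimated correlation could hardly call any list, so a call missing there says little. With the preset correlation its p rests on the spread among genes and not on that among libraries. A call over time in that form therefore does not show a change beyond differences between libraries. Of 466 entries in all lists, 443 were found among the gene symbols and 23 were not. The standard error of a log2 fold was taken as the fold over the root of the F statistic. A ribosomal protein gene is one with the symbol rpl or rps and a number. The kinases and the binding protein that share these letters are not among them, an exclusion made after a kinase had been counted at first.

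The comparisons, tests, gene lists, marker lists, the alternatives and the rule for named genes were fixed before the data were examined. In osteoblast-like nuclei the rule takes, among genes past the threshold whose 5 dpa value lies on the same side of both 3 dpa libraries, up to 10 per direction by the smaller of their folds against the 3 dpa libraries. With fewer than 20 genes past the threshold it takes any gene of at least 30 UMIs. Other classes have up to 3 per direction, each list its 4 members with the most UMIs and up to 6 called ones, and each comparison of classes the 6 list genes with the smallest p per direction. The genes snai2, twist2, zeb1a, zeb2a, zeb2b, cdh1, cdh2 and cdh11 are given whatever their values, and ribosomal, mitochondrial and unnamed genes are passed over.

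The tests were tried on simulated data of the same design and depth, with 100 genes changed 2-fold and 100 changed 4-fold. For osteoblast-like nuclei over time, 0 and 30 of them were recovered with 5 false calls among 35. For all nuclei 3 and 47 were recovered with 15 false calls among 65, so the share of false calls in the time comparisons was above the nominal one. For osteoblast-like against basal epidermis-like nuclei 68 and 100 were recovered with 8 false calls among 176, and against fibroblast-like nuclei 70 and 100 with 9 among 179.

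Alternatives tried were DESeq2's size factors in edgeR, DESeq2's Wald test, no filter on low counts, a minimum of 400 UMIs, Leiden resolution 2, list genes allowed in clustering, no centring per library, doublets kept, no library block, each library left out, an estimated correlation and nuclei thinned to 200 UMIs. The omission of nuclei over 5000 UMIs and the interaction of time with class were added after the data were seen. Barcodes under 200 UMIs were left out of every comparison as too shallow to class. The unnamed clusters were left out of the comparisons of classes but are part of the values over all nuclei.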

Results

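Nuclei of regenerating adult zebrafish caudal fins were profiled by sci-RNA-seq3, a single-nucleus method in which RNA is barcoded over successive rounds of indexing. The series title names programs that resemble epithelial-to-mesenchymal transition (EMT) and its reverse (MET) in osteoblasts, the bone-forming cells of the fin rays. There were 3 libraries, each from a pool of fins of strain AB. A pilot library came from 25 fins at 3 days post amputation (dpa), a main library from 100 fins at 3 dpa, and 1 library from 100 fins at 5 dpa. The library was the replicate, so 3 dpa had 2 replicates and 5 dpa had 1. The files held 5380529 UMIs in the pilot library, 10434571 in the main 3 dpa library and 16606531 in the 5 dpa library. After removal of small barcodes and of the highest doublet scores, 3965, 6196 and 11514 nuclei remained in the same order. Barcodes of at least 200 UMIs held a median of 521, 432.5 and 469 UMIs, so single nuclei were shallow and values below are sums over the nuclei of a class, scaled to the UMIs of that class as CPM, the usual unit of UMI counts over library size.

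Clustering gave 21 clusters, and 8 cell classes could be named from marker genes fixed beforehand. Osteoblast-like nuclei, marked by sp7, runx2a, col10a1a, panx3 and ifitm5, made up 6.28% of the nuclei of the pilot library (95% Clopper-Pearson interval 5.54 to 7.08). They made up 6.54% (5.93 to 7.18) of the main 3 dpa library and 6.14% (5.71 to 6.59) of the 5 dpa library, and these intervals overlap. The shares depended on the clustering and were 10.4%, 9.91% and 9.79% when the EMT and epithelial genes were allowed in it. Basal epidermis-like nuclei, named after the innermost layer of the epidermis, had a share of 13.0% (12.4 to 13.7) at 5 dpa against 9.96% (9.05 to 10.9) and 8.97% (8.27 to 9.71) at 3 dpa. Superficial epidermis-like nuclei held 22.04%, 22.8% and 23.6%, fibroblast-like nuclei 14.3%, 15.8% and 15.07%, and macrophage-like nuclei 7.87%, 5.47% and 7.35% of the 3 libraries in the same order. Without centring per library in the clustering the fibroblast-like shares were 21.8%, 42.0% and 14.7% and the superficial epidermis-like ones 10.97%, 20.2% and 14.0%. Endothelial-like, pigment-like and mucous-like nuclei were each under 5% of every library. The clusters of a class were not held alike: that led by sult2st3 and abcb5 had 314 of 874, 928 of 1413 and 1500 of 2712 superficial epidermis-like nuclei, the other being led by hsd3b7, and that led by enam and frem2b had 180 of 395, 415 of 556 and 626 of 1501 basal epidermis-like nuclei. In fibroblast-like nuclei the cluster led by robo3 had 278 of 567, 549 of 980 and 1109 of 1735. The intervals cover counting error only, and shares were not tested between the days. Between 29.2% and 35.0% of the nuclei lay in 8 clusters that met no naming rule. One of these was led by the fin-fold genes and1 and and2 and the matrix genes tnc and vcana, and held 50.8% of all UMIs. It held 11.5%, 17.1% and 10.4% of the nuclei of the pilot, main 3 dpa and 5 dpa libraries. Its median doublet score, 0.0986, was the highest of the 21 clusters, so values over all nuclei rest largely on a cluster that may hold doublets.

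The first comparison asked how osteoblast-like nuclei changed between 3 and 5 dpa, with 249 and 405 nuclei in the pilot and main 3 dpa libraries and 707 at 5 dpa. RNA of col10a1b, which encodes type X collagen, fell from 4147 and 2862 CPM to 527 CPM, a fitted log2 fold of −2.81 ± 0.74 (SE, adjusted p = 0.0217). RNA of krt8, a keratin of simple epithelia, fell from 594 and 531 CPM to 117 CPM (log2 fold −2.35 ± 0.59, adjusted p = 0.0164). RNA of myo6a, which encodes the actin motor myosin VI, rose from 53.7 CPM (95% Poisson interval 29.3 to 90.0) and 37.5 CPM (19.4 to 65.4) to 613 CPM (557 to 674), a log2 fold of 3.68 ± 0.54 (adjusted p = 1.16e-07). Of 75 measured ribosomal protein genes 41 fell by edgeR and 17 by DESeq2, with a median log2 fold of −1.91 over all 75. Against the pilot library alone that median was −1.54, and against the main 3 dpa library alone −2.22.

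Beside myo6a, 7 other named genes qualified upward in osteoblast-like nuclei. They were gyg1a, a glycogenin that primes glycogen synthesis (log2 fold 2.72 ± 0.62, adjusted p = 0.00806), dacha, a dachshund-family transcriptional regulator (1.85 ± 0.50, adjusted p = 0.0232), and rps6ka5, a stress-activated kinase (2.23 ± 0.65, adjusted p = 0.0370). TENM2, a teneurin adhesion protein, had a log2 fold of 2.06 ± 0.60, colgalt2, a collagen galactosyltransferase, one of 1.73 ± 0.53, and the nucleotidase gene nt5c2l1 one of 1.73 ± 0.53. The ankyrin gene ank1a (ENSDARG00000059093) had no UMI in the pilot library, which allows up to 14.1 CPM, 25.0 CPM in the main 3 dpa library and 135 CPM at 5 dpa. For dacha the log2 fold was 3.17 against the pilot library and 1.176 against the main one, and for nt5c2l1 it was 3.74 and 0.91.

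The other named genes that fell were of several kinds. RNA of marcksb, an actin-binding substrate of protein kinase C, fell by 3.31 ± 0.69 on the log2 scale (adjusted p = 0.00248), that of lepb, a leptin, by 3.06 ± 0.64 (adjusted p = 0.00248), and that of the alpha-tubulin gene tuba1b by 3.00 ± 0.66 (adjusted p = 0.00615). The histone-binding gene rbbp4 fell by 3.20 ± 0.84, the respiratory chain gene cox7c by 2.78 ± 0.70, the aquaporin gene aqp8a.1 by 2.70 ± 0.74 and the alpha-tubulin gene tuba1a by 2.52 ± 0.74, with adjusted p between 0.0164 and 0.0387. RNA of zmpste24, the protease that matures prelamin A, went from 34.5 and 53.1 CPM to 2.85 CPM (95% Poisson interval 0.345 to 10.3), the last from 2 UMIs. For lepb the log2 fold was −2.41 against the pilot and −3.46 against the main 3 dpa library, and for marcksb −2.82 and −3.61. The gene aqp8a.1, with 21, 15 and 7 UMIs in the pilot, main 3 dpa and 5 dpa libraries, was among the leading genes of the endothelial-like cluster. Its log2 fold in the other named classes together was −1.805, so its fall is not shown to be one of osteoblast-like cells.

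In all, 12 genes rose and 150 fell of 6987 tested in osteoblast-like nuclei by edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment. DESeq2 called 1 rise and 41 falls, and 36 of its calls were among the 162 of edgeR. The test has 1 residual degree of freedom and takes the lone 5 dpa library to vary like the 3 dpa libraries, and the count fell to 1 gene with DESeq2's size factors in edgeR. It was 0 by edgeR with a minimum of 400 UMIs per nucleus (525 genes at unadjusted p under 0.05) and 0 when the EMT and epithelial genes were allowed in clustering (712 at unadjusted p under 0.05).

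**Figure D1:**
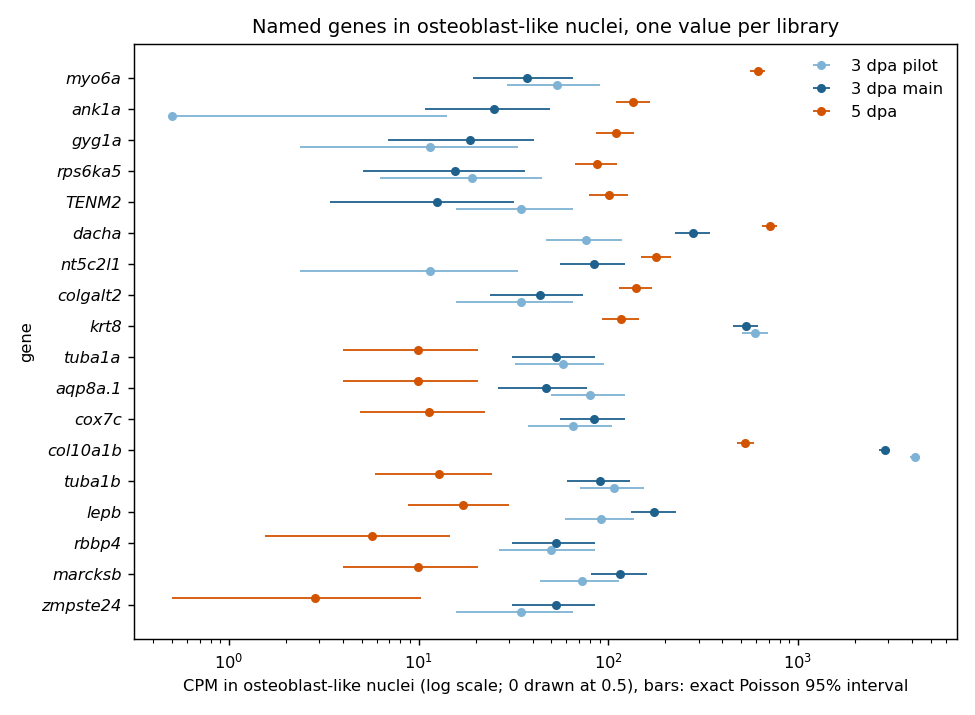
RNA level of the genes named by the fixed rule in osteoblast-like nuclei, in CPM on a log axis, with 1 point per library and exact Poisson 95% bars; values of 0 and lower bounds under 0.5 are drawn at 0.5. The 5 dpa point of myo6a lies at 613 CPM against 53.7 and 37.5 CPM at 3 dpa, and that of col10a1b at 527 CPM against 4147 and 2862 CPM.

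For the EMT and MET programs named in the title, gene lists were fixed before the data were examined. In osteoblast-like nuclei none of the 21 measured genes of the EMT list passed edgeR's threshold between 3 and 5 dpa; 2 had an unadjusted p under 0.05 and DESeq2 called 0. The count adjusted over the list alone was also 0, and the list's median log2 fold was −0.57, −0.13 against the pilot and −0.64 against the main 3 dpa library (camera, adjusted p = 0.186, and adjusted p = 0.80 with an estimated correlation). The mesenchymal cadherin gene cdh11 had 2978 and 1679 CPM at 3 dpa and 2747 CPM at 5 dpa, a log2 fold of 0.17 ± 0.63. Its log2 fold was −0.13 against the pilot and 0.55 against the main 3 dpa library, and twist2, snai2 and zeb1a also differed in sign between the 2. The EMT transcription factor genes stood at 0.24 ± 0.63 for snai2, −0.06 ± 0.53 for twist2, 0.10 ± 0.65 for zeb1a and 0.62 ± 0.51 for zeb2a, all with adjusted p of 0.806 or higher. The neural cadherin gene cdh2 had a log2 fold of −0.82 ± 0.53 (adjusted p = 0.678), and zeb2b, at 19.2, 21.8 and 18.5 CPM, was too low to test.

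Of 22 measured genes of the epithelial list, krt8 fell and none rose in osteoblast-like nuclei by edgeR, and DESeq2 called 2 falls. The count adjusted over the list alone was 2 falls, krt8 and krt18a.1, a keratin that pairs with it (log2 fold −1.80 ± 0.60). The epithelial cadherin gene cdh1 stood at 95.8 and 96.8 CPM at 3 dpa and 114 CPM at 5 dpa (log2 fold 0.15 ± 0.53, adjusted p = 0.945), and the plakophilin gene pkp3a had a log2 fold of 0.41 ± 0.52. The list's median log2 fold was 0.02, −0.34 against the pilot and 0.33 against the main 3 dpa library, while its mean was −0.19 and camera's direction was down (adjusted p = 0.931, and adjusted p = 0.955 with an estimated correlation). In simulated data of the same design the test found 0 of 100 genes changed 2-fold and 30 of 100 changed 4-fold, so smaller changes in these lists would have been missed.

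Among 12 measured cell cycle genes in osteoblast-like nuclei, the chromatin gene hmgb2a fell by 2.22 ± 0.60 on the log2 scale (edgeR, adjusted p = 0.0232), the 1 call of the list, and DESeq2 called 0. There were 4 falls adjusted over the list alone, hmgb2a, hmgb2b, mki67, the gene of the proliferation marker Ki-67, and pcna, the DNA polymerase clamp. The list's median log2 fold was −1.42, −1.15 against the pilot and −1.67 against the main 3 dpa library. Camera called the list lower at 5 dpa (adjusted p = 1.15e-05), but not with an estimated correlation (adjusted p = 0.80). That second form could hardly call any list at 1 residual degree of freedom, so its outcome says little about this one. The structural gene smc4, the list's member with the most UMIs, had a log2 fold of −0.18 ± 0.52.

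Among 19 measured genes of bone matrix and mineralization, col10a1b fell and none rose by edgeR, and DESeq2 called 3 falls. With p adjusted over the list alone 2 fell, col10a1b and ifitm5, a gene of mineralizing osteoblasts (−1.71 ± 0.58). The type I collagen genes col1a1a and col1a2 had log2 folds of −1.76 ± 0.90 (adjusted p = 0.431) and −1.70 ± 0.86 (adjusted p = 0.414), with col1a1a at 9115 CPM in the pilot, 24909 CPM in the main 3 dpa and 5445 CPM in the 5 dpa library. The list's median log2 fold was −0.75, −0.49 against the pilot and −1.11 against the main 3 dpa library. Camera called it lower (adjusted p = 0.00232), but not with an estimated correlation (adjusted p = 0.80), where hardly any list could pass.

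Among 16 measured genes of blastema and matrix turnover, 3 fell by edgeR and 1 by DESeq2. Those of edgeR were hapln1a, a link protein of the hyaluronan matrix (−2.62 ± 0.59), vcana, the proteoglycan versican (−2.03 ± 0.58), and timp2b, an inhibitor of metalloproteinases (−2.02 ± 0.59). Against the pilot and the main 3 dpa library alone the log2 folds were −1.83 and −3.12 for hapln1a, −0.85 and −2.67 for vcana and −1.52 and −2.38 for timp2b. Adjusted over the list alone 1 rose, the crosslinking enzyme gene loxl2a, and 5 fell. The list missed the threshold in camera (adjusted p = 0.0545, and adjusted p = 0.80 with an estimated correlation), with a median log2 fold of −0.82, −0.23 against the pilot and −1.15 against the main 3 dpa library. The fin-fold gene and1 had 1257 CPM in the pilot, 6973 CPM in the main 3 dpa and 1561 CPM in the 5 dpa library, so the 3 dpa libraries differed more from each other than the pilot did from 5 dpa. The tenascin gene tnc did the same, with 905, 2947 and 686 CPM, and so did vcana, with 295, 946 and 165 CPM.

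The 9 other lists held no gene past edgeR's threshold in osteoblast-like nuclei, and no list among them passed in camera. Only 1 gene of these lists passed when adjusted over the list alone, the BMP receptor gene bmpr1ba (−1.68 ± 0.56, adjusted p over all genes = 0.0775). Their counts at unadjusted p under 0.05 were 2 for BMP, 2 for retinoic acid, 1 for planar adhesion and cytoskeleton and 0 for the rest, and DESeq2 called 0 in each. Osteoblast commitment genes had a median log2 fold of 0.42 over 11 genes (0.09 against the pilot and 0.56 against the main 3 dpa library), with the bone transcription factor genes runx2a at 0.46 ± 0.64 and runx2b at 0.56 ± 0.55. The medians were 0.29 for 15 WNT genes (lef1 0.75 ± 0.52, wnt5b 0.57 ± 0.53), 0.20 for 11 hedgehog genes (gli2a 0.10 ± 0.56) and 0.17 for 16 FGF genes (fgfr1a 0.58 ± 0.51). They were −0.25 for 15 BMP genes (id1 −0.88 ± 0.53), −0.05 for 13 retinoic acid genes (rarga 0.48 ± 0.60), −0.03 for 21 genes of planar adhesion and cytoskeleton (ctnnb1 −0.51 ± 0.53) and −0.82 for 7 inflammation genes (stat3 −0.18 ± 0.52). The 7 Notch genes (notch2 −0.03 ± 0.52) had a median of −0.01 and a mean of −0.08 while camera's direction was up (adjusted p = 0.945).

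The same comparison in the other classes asked which of these changes belonged to osteoblast-like nuclei. The gene myo6a rose in 7 of 8 classes, among them basal epidermis-like (log2 fold 3.42, adjusted p = 1.77e-09), macrophage-like (3.88, adjusted p = 1.28e-10) and fibroblast-like nuclei (3.57, adjusted p = 0.00349). The collagen gene col10a1b fell in 4 of 8 classes, by 3.92 on the log2 scale in basal epidermis-like and by 2.85 in endothelial-like nuclei, where its level was at most 403 CPM. The matrix genes hapln1a and vcana each fell in 5 of 8 classes, and igf2b, a growth factor, in 5 of 7. In barcodes of at least 30 but under 200 UMIs hapln1a was lower at 5 dpa as well, with 367, 264 and 65.3 CPM in the pilot, main 3 dpa and 5 dpa libraries. Both matrix genes were among the 10 leading genes of the unnamed cluster led by and1. The glycogenin gene gyg1a rose in 4 of 6 classes and ank1a in 4 of 7. The keratin gene krt8 fell in 3 of 8 classes, with a log2 fold of −1.53 in the other classes together. Ribosomal protein genes fell in 63 of 75 cases in basal epidermis-like, 55 of 74 in macrophage-like, 5 of 73 in pigment-like and 2 of 57 in mucous-like nuclei by edgeR, where DESeq2 called 17, 4, 0 and 0. By edgeR 0 fell in endothelial-like, fibroblast-like and superficial epidermis-like nuclei (65, 71 and 59 at unadjusted p under 0.05, and 0 by DESeq2 in each) and 0 over all nuclei (76 at unadjusted p under 0.05, and 57 by DESeq2). Their median log2 fold lay between −1.85 and −1.45 in the 7 classes other than osteoblast-like nuclei. UMIs of the mitochondrial genome made up 0.867% of the pilot, 1.95% of the main 3 dpa and 0.608% of the 5 dpa library.

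Some genes stood out in other classes. In basal epidermis-like nuclei thsd7bb rose (3.99 ± 0.58, adjusted p = 1.51e-08), a leading gene of a cluster that held 64 of 395, 67 of 556 and 391 of 1501 nuclei of this class in the pilot, main 3 dpa and 5 dpa libraries, and tph1b, a tryptophan hydroxylase gene, fell (−3.29 ± 0.91, adjusted p = 0.0129). The gene tph1b is a marker of fibroblast-like nuclei, where it was higher, at 153 and 71.6 CPM at 3 dpa against 50.9 and 35.1 CPM, and its log2 fold was −3.50 (adjusted p = 0.0704). In macrophage-like nuclei the WNT modulator gene sfrp2 fell from 129 and 89.4 CPM to 2.06 CPM (95% Poisson interval 0.0522 to 11.5), the last from 1 UMI. In superficial epidermis-like nuclei XRCC2, a DNA repair gene, had no UMI in either 3 dpa library and 39.5 CPM at 5 dpa, a change past the threshold (adjusted p = 1.25e-05). Fibroblast-like nuclei likewise had 0, 0 and 34.4 CPM of XRCC2 in the pilot, main 3 dpa and 5 dpa libraries. Over all nuclei it had 1.06, 0.978 and 33.9 CPM, and sfrp2 was called over all nuclei too, so neither change is shown to be particular to 1 class. Camera called the EMT list lower in macrophage-like (adjusted p = 0.0134) and superficial epidermis-like nuclei (adjusted p = 8.38e-05) and over all nuclei (adjusted p = 0.0192), calls lost with an estimated correlation (adjusted p = 0.856, 0.485 and 0.828). It called the cell cycle list lower in all 6 other classes in which it was tested, the bone matrix list in all 7, the blastema list in 6 of 7 and the inflammation list in superficial epidermis-like nuclei, and each of these calls was lost with an estimated correlation (smallest adjusted p = 0.485). The 3 dpa libraries stood apart in these lists: where called, blastema medians were between −0.70 and −0.23 against the pilot and between −2.14 and −1.11 against the main 3 dpa library, bone matrix medians between −1.03 and −0.20 and between −1.83 and −1.14, and cell cycle medians between −1.28 and −0.35 and between −1.91 and −1.01. Over all nuclei these 4 lists were lower as well (cell cycle, adjusted p = 2.79e-10), and these calls too were lost with an estimated correlation (cell cycle, adjusted p = 0.828). With 1 residual degree of freedom that form could hardly call any list, so these losses say little. The calls with the preset correlation of 0.01 do not measure spread among libraries either. For the cell cycle list over all nuclei the estimated correlation was 0.867.

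By edgeR's quasi-likelihood test 114 genes rose and 293 fell of 7492 in basal epidermis-like nuclei, and 15 rose and 163 fell of 5053 in macrophage-like nuclei, where DESeq2 called 9 and 43, and 0 and 13. Endothelial-like nuclei had 4 rises, among them myo6a, ank1a and aldh1a3, and 8 falls, and pigment-like nuclei 3 rises, among them myo6a and nt5c2l1, and 15 falls. Fibroblast-like nuclei had 2 rises, myo6a and gabbr2, and 0 falls (845 genes at unadjusted p under 0.05; DESeq2 1 and 0). Superficial epidermis-like nuclei had 5 rises, gyg1a, XRCC2, myo6a and 2 genes with clone names, and 2 falls, igf2b and hapln1a. DESeq2 called 0 genes in endothelial-like, pigment-like and superficial epidermis-like nuclei (498, 231 and 698 at unadjusted p under 0.05 by edgeR). Mucous-like nuclei had 0 rises and 4 falls, rpl19, rpl4, TXN and vcana (118 genes at unadjusted p under 0.05; DESeq2 0). Genes named only because their count was small were chosen after their values were seen. Over all nuclei 13 rose and 4 fell of 18256, among them XRCC2 (4.94 ± 0.47), the chloride channel gene cftr (3.84 ± 0.51), myo6a (3.20 ± 0.33), tph1b (−3.32 ± 0.49), col10a1b (−2.83 ± 0.40), igf2b and sfrp2, and DESeq2 called 22 and 168. That count of 17 was 0 by edgeR without nuclei over 5000 UMIs (1946 at unadjusted p under 0.05), 2 with doublets kept, 882 without the filter on low counts and 382 with DESeq2's size factors. An interaction of time with class, chosen after the data were seen, tested whether the change in osteoblast-like nuclei differed from that in the other named classes together. It called 0 of 11488 genes by edgeR, with 340 at unadjusted p under 0.05 and no other tool run. Of the 162 genes called in osteoblast-like nuclei, 12 were also called in the other classes together, which come from the same 3 libraries. All 162 were measured there and all 162 changed in the same direction as in osteoblast-like nuclei, so the other 150 are not shown to be particular to them.

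**Figure D2:**
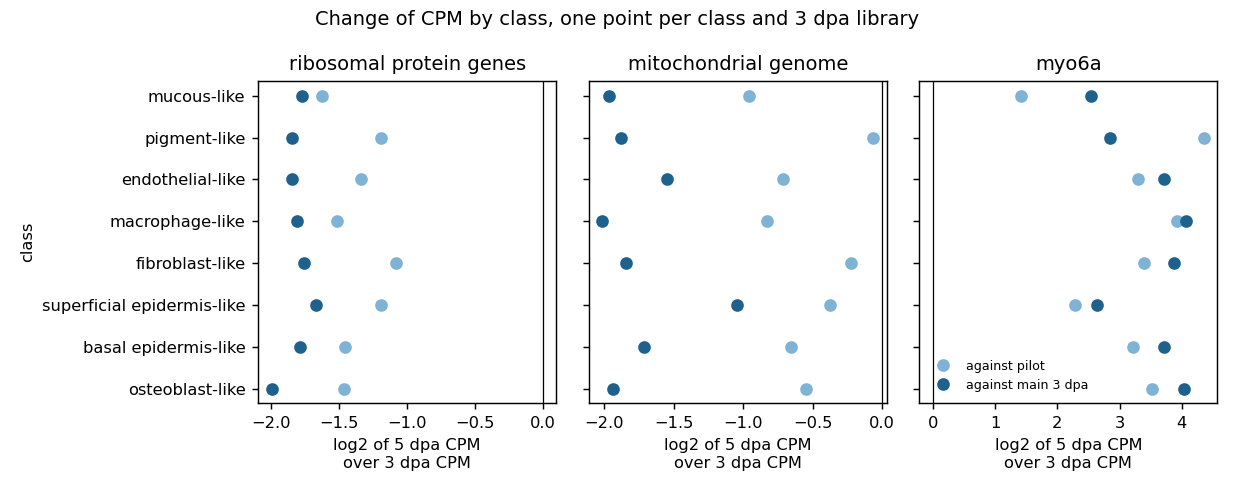
Log2 ratio of the 5 dpa CPM to the CPM of each 3 dpa library, per class, for ribosomal protein genes together, the mitochondrial genome and myo6a, with 1 point per 3 dpa library and no error bars. In osteoblast-like nuclei the ribosomal protein ratio was −1.46 against the pilot and −2.00 against the main 3 dpa library.

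The second comparison asked where osteoblast-like nuclei stand between epithelial and mesenchymal classes of the same libraries, with the library as a block and n = 3. Against basal epidermis-like nuclei, 9 of 18 measured EMT list genes were higher and 3 lower in osteoblast-like nuclei. The cadherin gene cdh11 had 2468 ± 693 CPM (SD, n = 3) against 171 ± 30.9 CPM, a log2 fold of 3.94 ± 0.19 (edgeR, adjusted p = 3.93e-15). The EMT transcription factor gene zeb2a had 454 ± 160 against 78.8 ± 5.38 CPM (log2 fold 2.61 ± 0.20), twist2 a log2 fold of 1.95 ± 0.24, zeb1b one of 1.74 ± 0.19 and twist3 one of 1.73 ± 0.31. The genes on the list that were lower were the fibronectin gene fn1b (−2.22 ± 0.16, adjusted p = 1.26e-11), the collagenase gene mmp2 (−0.56 ± 0.19) and tgfb3 (−0.77 ± 0.28), while snai2 did not differ past the threshold (0.24 ± 0.35).

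Of 30 measured epithelial list genes, 22 were lower and 3 higher in osteoblast-like than in basal epidermis-like nuclei. The epithelial cadherin gene cdh1 had 102 ± 10.1 CPM (SD, n = 3) against 592 ± 26.5 CPM (log2 fold −2.45 ± 0.19, edgeR, adjusted p = 2.63e-11), and epcam, an epithelial adhesion gene, 68.8 ± 17.97 against 404 ± 41.3 CPM (−2.56 ± 0.22). The claudin gene cldn1 (−2.95 ± 0.35), the epithelial transcription factor gene grhl2b (−2.53 ± 0.32) and the protease inhibitor genes spint2 (−2.42 ± 0.33) and spint1a (−1.67 ± 0.24) were lower too. The genes that were higher were jupb, one of a pair of plakoglobin genes, with 89.2 ± 35.3 against 13.1 ± 2.78 CPM (2.93 ± 0.34, adjusted p = 8.9e-08), the keratin gene krt18b (1.15 ± 0.20) and the tight junction gene tjp1a (0.79 ± 0.25).

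Adjusted over the list alone, 9 EMT genes were higher and 3 lower, and 3 epithelial genes were higher and 23 lower. By limma's fry the EMT list had a common upward direction (adjusted p = 0.0144) and the epithelial list a downward one (adjusted p = 0.0415). Over all genes 2057 of 6222 passed. Without the library block 6 EMT and 14 epithelial genes passed.

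Against fibroblast-like nuclei, the other mesenchymal class, the EMT list split. Osteoblast-like nuclei were higher for 4 of 22 measured genes, cdh11 (log2 fold 4.38 ± 0.17, edgeR, adjusted p = 5.13e-34), zeb2a (2.88 ± 0.18), twist2 (1.06 ± 0.20) and zeb1b (0.80 ± 0.15). They were lower for 7, among them tgfbi, a matrix protein induced by TGF-beta (−1.84 ± 0.17), cdh2, with 290 ± 84.8 against 576 ± 117 CPM (SD) in 3 libraries (−1.04 ± 0.14), the metalloproteinase gene mmp14b (−0.73 ± 0.14), tgfb2 (−0.75 ± 0.16) and the integrin gene itga5 (−0.60 ± 0.14). Of 21 measured epithelial list genes 9 were higher in osteoblast-like nuclei, led by jupb (2.23 ± 0.28, adjusted p = 8.61e-10), pkp3a (0.72 ± 0.15), the epithelial splicing regulator genes esrp1 (0.95 ± 0.22) and esrp2 (1.178 ± 0.33), the polarity gene llgl2 (0.96 ± 0.23) and klf4 (0.90 ± 0.25). None was lower past the threshold in edgeR, 11 of the 21 had an unadjusted p under 0.05, and DESeq2 called 2 in all. The genes cdh1 (0.48 ± 0.21, adjusted p = 0.109) and epcam (0.27 ± 0.24) did not pass.

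The counts adjusted over the list alone were also 4 higher and 7 lower for the EMT list and 9 higher for the epithelial list, and 1369 of 7093 genes passed over all. The EMT list had a median log2 fold of −0.30 while the direction by limma's fry was up (adjusted p = 0.915, and adjusted p = 0.00522 for change in either direction), and the epithelial list had an adjusted p of 0.158 for a common direction. The epithelial count of 9 fell to 1 without centring per library in the clustering, to 1 without the library block, to 3 without the 5 dpa library and to 4 without the pilot library. Without the block the EMT count of 11 fell to 2, and without the 5 dpa library to 7.

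**Figure D3:**
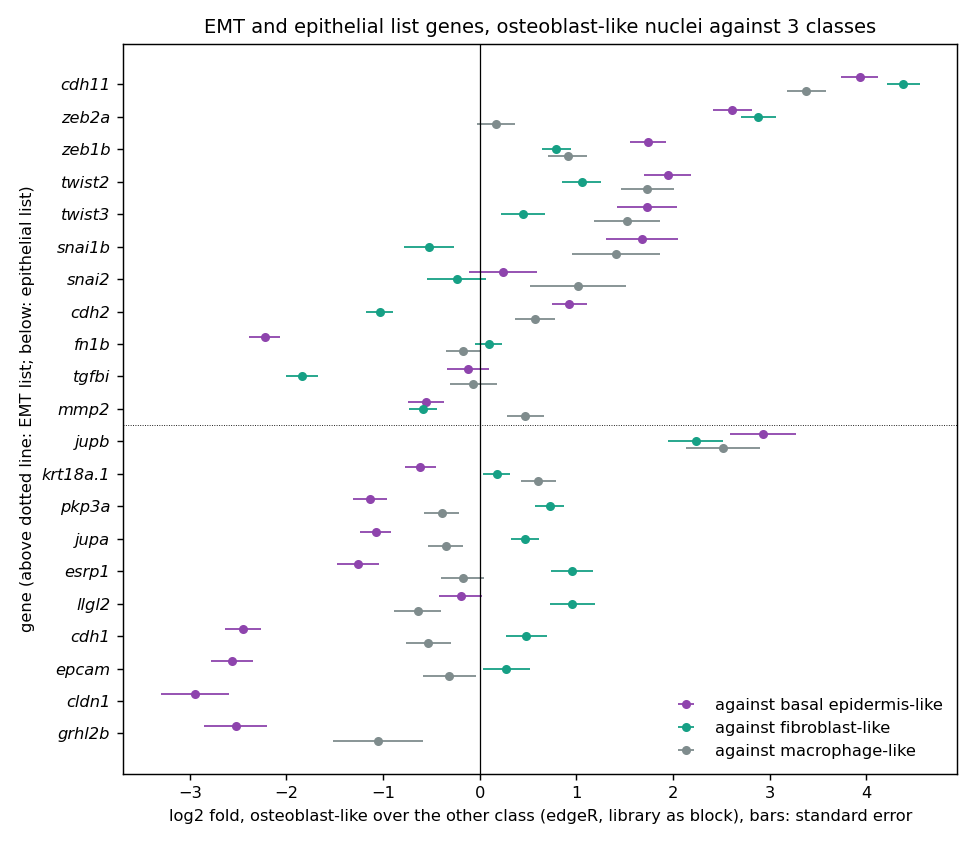
Fitted log2 fold with its SE for genes of the EMT list (above the dotted line) and the epithelial list (below it), osteoblast-like nuclei against basal epidermis-like, fibroblast-like and macrophage-like nuclei of the same 3 libraries; the genes shown were picked after their values were seen. The gene cdh11 lies at 3.94, 4.38 and 3.38 and jupb at 2.93, 2.23 and 2.52, while cdh1 lies at −2.45 against basal epidermis-like nuclei.

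Macrophage-like nuclei, of an immune class, served as a reference for epithelial RNA from other cells, though their level was not shown to be that of free RNA. For cdh1 it was 194, 179 and 163 CPM, against 353, 334 and 386 CPM in barcodes of at least 30 but under 200 UMIs. Against this class, 3 of 23 measured epithelial list genes were higher in osteoblast-like nuclei. They were jupb, with 89.2 ± 35.3 against 19.5 ± 13.1 CPM (SD) in 3 libraries (log2 fold 2.52 ± 0.38, edgeR, adjusted p = 3.55e-08), the keratin gene krt18a.1 (0.61 ± 0.18) and tjp1a (0.80 ± 0.28). Another 4 were lower, spint1a (−0.88 ± 0.28), the junction gene f11r.1 (−0.90 ± 0.29), the polarity gene crb3a (−1.26 ± 0.44) and llgl2 (−0.64 ± 0.24). The genes cdh1 (−0.53 ± 0.23, adjusted p = 0.0609) and epcam (−0.31 ± 0.28) did not pass, and neither lay above the macrophage-like level. On the EMT list 9 of 19 genes were higher and 0 lower by edgeR (12 at unadjusted p under 0.05), led by cdh11 (3.38 ± 0.20) and twist2 (1.73 ± 0.27), while zeb2a, also a gene of macrophages, stood at 0.17 ± 0.20. Adjusted over the list alone the counts were 3 and 4 for the epithelial list and 10 higher for the EMT list. By limma's fry the EMT list had no common direction past the threshold (adjusted p = 0.0578), and 2140 of 5873 genes passed over all. The EMT count of 9 fell to 5 without the 5 dpa library and to 3 without the library block.

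Free RNA gives some nuclei a UMI of a gene they do not express, so the share of nuclei with a UMI was set beside that of macrophage-like nuclei. Median depths were 652, 469 and 614 UMIs in osteoblast-like and 397.5, 346 and 388.5 in macrophage-like nuclei of the pilot, main 3 dpa and 5 dpa libraries, so each nucleus was thinned to 200 UMIs. For cdh1 the share was then 2.41%, 1.98% and 2.55% of osteoblast-like, 4.17%, 1.47% and 1.65% of macrophage-like and 13.2%, 11.7% and 10.6% of basal epidermis-like nuclei. For cdh11 it was 46.2%, 29.6% and 43.1% of osteoblast-like against 6.73%, 5.01% and 3.31% of macrophage-like nuclei. For jupb it was 1.61%, 0.988% and 2.40% against 0%, 0.295% and 0.118%, with 95% Clopper-Pearson intervals that overlapped in both 3 dpa libraries. Without thinning jupb had 9.24%, 3.95% and 8.77% against 0.321%, 1.47% and 1.06%, cdh1 8.43%, 6.67% and 9.62% against 9.29%, 5.60% and 7.09%, and cdh11 73.9%, 54.3% and 73.4% against 11.5%, 9.73% and 7.33%. By limma's fry the epithelial list had no common direction past the threshold (adjusted p = 0.252). The epithelial count of 7 fell to 2 with DESeq2, to 1 without the library block, to 3 without the 5 dpa library and to 4 without the pilot library, and it was 13 with called doublets kept.

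Osteoblast-like nuclei formed 2 clusters, the larger of 968 nuclei and the smaller of 393 nuclei, which held 67 of 249, 99 of 405 and 227 of 707 osteoblast-like nuclei of the pilot, main 3 dpa and 5 dpa libraries. The smaller cluster was higher for twist2, with 281 ± 92.8 against 98.0 ± 26.6 CPM (SD) in 3 libraries (log2 fold 1.51 ± 0.25, edgeR, adjusted p = 2.37e-08), and for zeb2a (0.90 ± 0.19). It was lower for cdh11, with 1559 ± 434 against 2940 ± 918 CPM (−0.94 ± 0.16), and for fn1b (−0.63 ± 0.18). On the epithelial list it was higher for jupb, with 181 ± 75.4 against 41.1 ± 11.7 CPM (2.07 ± 0.33, adjusted p = 1.03e-08), and lower for krt18a.1 (−0.57 ± 0.18), while cdh1 (−0.49 ± 0.33) and epcam (0.32 ± 0.39) did not pass.

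So 2 EMT genes were higher and 2 lower of 16 measured, and 1 epithelial gene was higher and 1 lower of 16. Adjusted over the list alone the counts were 3 and 3, and 1 and 2. Over all genes 520 of 4143 passed. Without the library block the EMT count was 0 by edgeR and the epithelial count 1, and without either 3 dpa library the epithelial count was 1. No osteoblast marker was among the 10 leading genes of the smaller cluster, which were led by lmx1ba, kcnq5a, scube1, tnmd and pthlha, so its identity as osteoblast is less certain. The same held for both fibroblast-like clusters and 1 superficial epidermis-like cluster, which had 0 of their own markers among their 10 leading genes, while an unnamed cluster of 685 nuclei had runx2a and runx2b among them.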

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

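Except for the tests by depth of nuclei, whose expected outcomes were written beforehand, the tests below were chosen only after the results had been seen. One signal lay in data that no comparison used, the barcodes under 200 UMIs. Genes of red blood cells made up 0.0171% of the UMIs of these barcodes in the pilot 3 dpa library (95% Clopper-Pearson interval 0.0134 to 0.0216), 0.112% (0.107 to 0.117) in the main 3 dpa library and 0.173% (0.168 to 0.178) in the 5 dpa library. There were no control samples, and counts of 71, 1934 and 4274 UMIs are above what a count of 0 allows by their size alone, so this says little. The pattern was not confined to these barcodes, since the nuclei held 78.2, 329 and 679 CPM of the same genes, and the pilot file lists no barcode under 26 UMIs. These genes include 5 that were listed because they had been seen higher at 5 dpa, so part of the rise at 5 dpa follows from their choice. Over all nuclei the median log2 fold against the main 3 dpa library was 1.39 for these 5 and 0.603 for the 9 others.

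Ribosomal protein RNA was lower at 5 dpa in all 8 classes by median, with log2 folds between −1.91 and −1.45. A fixed amount of free RNA per barcode would dilute with depth. Over all classes together, ribosomal protein CPM in both 3 dpa libraries showed little such dilution. In nuclei of 1000 to 5000 UMIs it was at least 0.923 times that in nuclei of 200 to 400 UMIs. But depth went with class, as the unnamed cluster led by and1 had a median of 2302.5 UMIs, so unlike cells were compared. Pilot barcodes of at least 30 but under 200 UMIs held 36702 CPM against 23622 in its nuclei. Such barcodes held less than nuclei in the main 3 dpa library (27063 against 30865 CPM) and in the 5 dpa library (8732 against 9380 CPM). The libraries thus differed in direction, and this stays open. Cytoplasmic RNA carried along with nuclei may differ between libraries: the log2 fold of mitochondrial transcripts was 0.375 times that of ribosomal protein transcripts against the pilot and 0.980 times against the main 3 dpa library, which leaves this open. A biological change between 3 and 5 dpa is open as well, since the smaller log2 fold was 3.453 times the log2 difference of 0.386 between the 3 dpa libraries. With 1 library at 5 dpa, day and library preparation cannot be told apart for these genes.

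The gene myo6a and genes known from red blood cells were higher at 5 dpa, ank1a past edgeR's threshold in 4 classes and nt5c2l1 in 2, while alas2, epb41b and add2 passed in none. RNA of red blood cells may account for the erythroid genes: 9 others had a median log2 fold 0.433 times that of these 5 against the main 3 dpa library (0.546 before ank1a was added to the 5), but the most abundant, slc4a1a and hbaa1, a condition also added after that value was seen, stood at 0.06 and −0.05, so this stays open. For myo6a such RNA is argued against, since the main 3 dpa library held more erythroid RNA than the pilot by 2.07 on the log2 scale and less myo6a (−0.346). For free RNA in a fixed amount per barcode, the ratio between deep and shallow nuclei at 5 dpa was 0.921, little dilution over all classes together. But these bins mix classes of unlike depth, and nuclei over 5000 UMIs held less (468 against 694 CPM at 200 to 400 UMIs). Barcodes of at least 30 but under 200 UMIs held more myo6a than nuclei (876 against 567 CPM), so the ratio does not decide this. A variant or allele of myo6a carried by the fish of the 5 dpa library could raise it alike in all classes, and the classes' log2 folds spanned 2.008, from 1.98 to 3.99, which does not decide it. No biological explanation beyond the day itself was tested, and the day is shared with the library.

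Some epithelial genes were found in osteoblast-like nuclei. Free epidermal RNA would keep the proportions of basal epidermis-like nuclei, and jupb, 1 of 3 genes above the macrophage-like level, was higher in osteoblast-like nuclei by a log2 fold of 2.933, which argues against that source for jupb. The 20 remaining measured genes had a median log2 fold of −0.351 against macrophage-like nuclei, with 5 above 0, so free RNA may account for them, although the macrophage-like level was not shown to be that of free RNA. A fixed amount per barcode would also be diluted more in osteoblast-like nuclei, which were deeper. Their median depths were 652, 469 and 614 UMIs against 397.5, 346 and 388.5. A median under 0 therefore does not decide this. Doublets with epidermal nuclei are argued against as the source of jupb, since cdh1 reached 17.2% of its basal level and jupb 682%, a ratio of 0.0253. Expression of jupb by osteoblast-like cells is a hypothesis found and tested on the same data. It rests mostly on the smaller osteoblast-like cluster (181 against 41.1 CPM in the larger), which has no osteoblast marker among its 10 leading genes and may be another cell type. In the pilot, main 3 dpa and 5 dpa libraries jupb had 35.3, 26.5 and 40.8 CPM over all nuclei. It had 60.1, 32.1 and 45.9 CPM in endothelial-like and 53.7, 26.1 and 47.1 CPM in pigment-like nuclei, on 12 UMIs or fewer each. Superficial epidermis-like nuclei held less (9.41, 6.33 and 13.2 CPM). The larger cluster is thus not shown to hold more jupb than the tissue at large.

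For the comparisons of classes, the 6 sums of each were split in the 10 possible ways into groups of 3, too few for a share under 0.05. The real split gave 12 EMT and 25 epithelial genes against basal epidermis-like, 11 and 9 against fibroblast-like, 9 and 7 against macrophage-like nuclei and 4 and 2 between the sub-clusters by edgeR, while the highest other split gave 0 in each, so that 1 split in each reached the real count. Every other split has sums of both classes on each side, so the class difference adds to its residual spread. A count of 0 there was nearly assured and lends the real split no support.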

How the results depend on the processing

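The tests without nuclei over 5000 UMIs were chosen only after the data were seen, as were the share of doublets removed and the shares of nuclei with list genes in clustering, and the other settings were planned. No paired analysis was possible because the time points share 1 library number, which is only the order of deposit. Leaving out the 5 dpa library leaves no time comparison, and leaving out a 3 dpa library leaves folds without a test. The 18 genes named for the size of their change in osteoblast-like nuclei and the 2 called lists kept their direction in these folds, and the 18 genes in the other settings run. Genes given for their lists did not all do so: against the pilot alone and1 (fitted −1.53) stood at 0.30, cdh11 (0.17) at −0.13, twist2 (−0.06) at 0.44, snai2 (0.24) at −0.08 and notch2 (−0.03) at 0.26, and against the main 3 dpa library alone zeb1a (0.10) stood at −0.42. The sub-cluster comparison was not run at resolution 2, with list genes in clustering, without centring or with doublets kept, because the clusters themselves change. The cause of the changes below was not tested.

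Genes called over time in osteoblast-like nuclei (162) were 1 with DESeq2's size factors, 42 with DESeq2, 32 without the filter on low counts, 0 with a minimum of 400 UMIs, 252 at Leiden resolution 2, 0 with list genes in clustering and 256 without centring. The 0 counts are edgeR's, with 525 and 712 genes at unadjusted p under 0.05. Of the 162, 36 were shared with DESeq2, 25 without the filter, 141 at resolution 2, 141 without centring, 148 with doublets kept and 135 without nuclei over 5000 UMIs. The sum of calls over the 7 other classes, each fitted by itself, was 628 and became 66 with DESeq2, 240 without the filter and 2101 without centring. Over all nuclei 17 became 382 with DESeq2's size factors, 190 with DESeq2, 882 without the filter, 9 with a minimum of 400 UMIs, 2 with doublets kept and 0 by edgeR without nuclei over 5000 UMIs (1946 at unadjusted p under 0.05). The 2 lists called by camera became 0 with an estimated correlation, a form that could hardly call any list at 1 residual degree of freedom.

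Without the library block, EMT and epithelial genes called against basal epidermis-like nuclei were 6 and 14 (12 and 25 with it), against fibroblast-like 2 and 1 (11 and 9), against macrophage-like 3 and 1 (9 and 7), and between sub-clusters 0 and 1 (4 and 2), with 5 EMT genes at unadjusted p under 0.05 behind edgeR's 0. With DESeq2 epithelial calls were 2 against fibroblast-like, 2 against macrophage-like nuclei and 1 between sub-clusters. They were 1 against fibroblast-like nuclei without centring and 13 against macrophage-like nuclei with doublets kept. With 1 library left out, EMT and epithelial counts ranged from 9 to 12 and 19 to 26 against basal epidermis-like, from 7 to 11 and 3 to 8 against fibroblast-like nuclei, from 5 to 9 and 3 to 7 against macrophage-like nuclei, and from 3 to 4 and 1 to 2 between sub-clusters. Epithelial counts were 4 without the pilot library and 3 without the 5 dpa library against both fibroblast-like and macrophage-like nuclei, and 1 without either 3 dpa library between sub-clusters, and the EMT counts of 7 against fibroblast-like and 5 against macrophage-like nuclei were without the 5 dpa library.

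The osteoblast-like share was 7.44%, 8.02% and 7.10% at resolution 2, 10.4%, 8.96% and 9.02% without centring, 9.91%, 9.51% and 9.39% with doublets kept and 10.4%, 9.91% and 9.79% with list genes in clustering in the pilot, main 3 dpa and 5 dpa libraries. With a minimum of 400 UMIs it was 7.35% in the main 3 dpa and 7.64% in the 5 dpa library. Of the 18 named genes, 17 lost their call with DESeq2's size factors, 15 with DESeq2, 18 with a minimum of 400 UMIs, 18 with list genes in clustering, 10 without the filter, 4 at resolution 2, 4 without centring, 5 with doublets kept and 6 without nuclei over 5000 UMIs. Shares of other classes left their interval in 10 cases at resolution 2 (4 higher, 6 lower), 8 with doublets kept (3 and 5), 11 with a minimum of 400 UMIs (4 and 7), 7 without centring (2 and 5, among them fibroblast-like nuclei at 42.0% of the main 3 dpa library) and 3 with list genes in clustering (1 and 2). Of 39 shares of osteoblast-like nuclei with a UMI, 37 fell below their interval in nuclei thinned to 200 UMIs. Thinning can only keep or lower such a share, so this fall says nothing about the stability of the shares.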

Other observations

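The gene lists of this part were written after some of their values had been seen. Over all nuclei some genes known to respond to glucocorticoids had higher values at 5 dpa than in both 3 dpa libraries. The chaperone gene fkbp5 stood at 922, 824 and 2123 CPM in the pilot, main 3 dpa and 5 dpa libraries (edgeR, log2 fold 1.20 ± 0.35, adjusted p = 0.134), and the transcription factor gene zbtb16a at 1592, 1053 and 2350 CPM. All 6 genes of that list were higher than in both, as were 36.3% of all 18256 tested genes, but tsc22d3 by 0.14 ± 0.36 only, and 0 passed edgeR's threshold (4 at unadjusted p under 0.05, and 0 by DESeq2). The lists were not tested for enrichment. Of 9 genes of the circadian clock 7 were higher at 5 dpa than in both, among them nr1d2a (log2 fold 1.26 ± 0.33, adjusted p = 0.103), and 0 passed in edgeR (2 at unadjusted p under 0.05, and 0 by DESeq2). The labels give no hour of collection.

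Of 9 genes known to respond to hypoxia 4 were far higher in the main 3 dpa library than in the pilot, a difference that was not tested. The oxygen-sensing hydroxylase gene egln3 had 1.91 CPM in the pilot, 87.8 in the main 3 dpa and 2.29 in the 5 dpa library, ankrd37 had 1.06, 19.1 and 0.382 CPM, and the lactate dehydrogenase gene ldha 37.8, 120 and 14.5 CPM. The collagen hydroxylase gene p4ha1b had 43.2, 198.8 and 17.4 CPM, while the vascular growth factor gene vegfaa, at 47.6, 41.0 and 48.2 CPM, and pdk1 and bnip3 were not highest in the main 3 dpa library, and slc2a1b (88.0, 125 and 105 CPM) and pfkfb3 (24.5, 47.2 and 27.7 CPM) differed less. By edgeR 0 of the 9 listed genes passed between 3 and 5 dpa, with 1 at unadjusted p under 0.05, bnip3, while DESeq2 called 1, ldha.

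Over all nuclei the anion exchanger gene slc4a1a of red blood cells had 5.74, 45.7 and 55.8 CPM and the globin gene hbaa1 10.6, 48.4 and 54.7 CPM in the pilot, main 3 dpa and 5 dpa libraries. Of 9 such genes 6 were higher at 5 dpa than in both 3 dpa libraries and 1 was lower than in both, with 0 past edgeR's threshold (1 at unadjusted p under 0.05, and 0 by DESeq2). Of the 5 erythroid genes first seen higher, edgeR called 0 over all nuclei (2 at unadjusted p under 0.05), and DESeq2 called 1, ank1a.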
